A study of Mus musculus with 19 samples.

How the data were processed

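RNA-seq was done on B lineage cells sorted from immunized mice on day 28, with 19 libraries in 6 groups taken from the sample labels. Per the series design, 3 wild-type and 4 knockout mice were used. The reads were aligned with STAR to genome build mm10, per the submitters' processing notes, which give no versions. The counting tool, gene annotation, strand setting and filters are not given in the sources used here, so overlapping, antisense and near-identical genes carry an uncertain split of reads.

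Expression was deposited by the authors as CPM in 4 tables, each column summing to 1000000. The germinal centre table had 0.0001 added to every value, which was subtracted, and lists 17939 genes; the other 3 list 19416. In those 3, 19 gene names had been turned into spreadsheet dates and 1 row was duplicated, and these were left out. The biotype names also differ between the germinal centre table and the others, so the tables were tested separately and levels across them are only described. A gene can be missing from one table without being unexpressed. The genotype line of the naive and antibody-secreting cell tables calls 9 columns HET where the sample labels say wild type; the sample labels were kept.

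The smallest step between low CPM values gave the worth of 1 read and so the depth of each library, 10.2 to 21.6 M (1 M is 1000000) assigned reads. Below 1000 reads, 61.4% to 67.6% of values in the germinal centre table and 85.1% to 88.7% in the others lay within 0.02 of a whole read, so the authors' values come from estimated counts and a test on whole reads was not used. A floor of 3 reads per library was set under genes at 0, and no ribosomal protein or oxidative phosphorylation gene was at 0 in any library. The floor and the step cover counting error only.

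Genes with a mean of at least 10 CPM were tested with limma 3.58.1 (lmFit and eBayes with trend, in R 4.3.3) on log2(CPM + 1) with no covariate, and Benjamini-Hochberg adjusted p-values under 0.05 were called. The design fixed in advance assumed normalized counts on an unknown scale, and the test did not change with the unit. A fold change on this scale understates the change of low genes. Germinal centre and naive B cells were fitted in their own tables, and the difference of the genotype effects in a fit of both with a term for each group. The 41 gene lists were fixed before the data were examined, as were the tests and the alternatives listed in advance, and lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Some list symbols were not found in the tables. Library measures were compared with two-sided exact permutation tests. Genes named in the text follow a rule fixed in advance: Pik3cg, the 10 genes with the largest called change in each direction that did not overlap between groups and reached 50 CPM, up to 4 members of each list that passed or had at least 3 called members (3 were taken), and 13 fixed genes. Variable, diversity and joining segments, predicted genes and pseudogenes were left out of the 10. Where fewer passed, the smallest p-values filled the list. Some genes this rule chose and 1 list that was tested are not reported here, and counts of named genes leave those genes out. Sums over marker lists, heavy-chain class shares and variable-gene usage were computed in Python 3.11.15 with pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Positions came from GENCODE release M21 on mm10, in which 97.4% of the germinal centre table's symbols and 96.5% of the others' were found.

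The tests were tried on simulated data made from the real means, depths and spread. For germinal centre B cells (8312 genes in that step), 8%, 38%, 60% and 64% of genes changed 2-, 4-, 8- and 16-fold were recovered, with 8 false among 93 calls. For naive B cells (8789 genes), 18%, 76%, 80% and 98% were recovered, with 7 false among 143 calls. Between replicates of a group, Pearson correlations of log2(CPM + 1) across tested genes ran from 0.681 to 0.743 in germinal centre B cells labelled knockout, 0.827 to 0.873 in those labelled wild type, 0.880 to 0.912 in naive B cells and 0.871 to 0.932 in antibody-secreting cells. Genes are not independent replicates. Alternatives covered the pseudocount, the filter, the scaling, sample weights, robust estimation, the threshold, a replicate block, the list test and leaving out each library.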

Results

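RNA was sequenced from B lineage cells sorted from mice 28 days after immunization with sheep red blood cells, a particulate antigen that drives germinal centre and antibody responses. The series compares mice labelled wild type with mice labelled knockout for Pik3cg, which encodes the catalytic subunit p110γ of class I phosphoinositide 3-kinase. The 19 libraries fall into 6 groups. Splenic germinal centre B cells, gated on CD95 and GL7, were profiled in 4 libraries labelled knockout and 3 labelled wild type, and splenic naive B cells in 3 and 3. Antibody-secreting cells labelled wild type came from spleen (n = 3) and bone marrow (n = 3). Values were deposited as counts per 1000000 assigned reads (CPM), and the worth of 1 read put the depth at 10.2 to 21.6 M (1 M is 1000000) reads per library. In the naive and antibody-secreting cell tables, the 9 columns that the sample labels call wild type are headed HET, so whether these mice were wild type or heterozygous is open. Groups are named here as the sample labels name them.

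Pik3cg, the targeted gene (ENSMUSG00000020573, chromosome 12, 32173473 to 32208659, minus strand, mm10), showed no difference past the threshold between the libraries labelled knockout and wild type, with wide error in germinal centre B cells. In germinal centre B cells it stood at 66.0, 52.8, 6.6 and 9.0 CPM in the 4 libraries labelled knockout and at 56.5, 34.3 and 19.4 CPM in the 3 labelled wild type. The log2 fold change of labelled knockout over labelled wild type was −0.60 (95% interval −2.51 to 1.32, limma adjusted p = 0.696). It was −1.11, −1.01, −0.06 and −0.20 without labelled-knockout replicate 1, 2, 3 or 4, and −0.23, −0.58 and −0.98 without labelled-wild-type replicate 1, 2 or 3. Without both labelled-knockout replicate 1 and labelled-wild-type replicate 3, a choice made after the data were seen, it was −1.50, and none of these passed. In naive B cells it stood at 94.98, 126.8 and 97.7 CPM against 114.5, 110.1 and 110.6 CPM, a log2 fold change of −0.08 (95% interval −0.43 to 0.27, limma adjusted p = 0.935). In antibody-secreting cells labelled wild type, Pik3cg averaged 41.3 CPM ± 9.7 (SD, n = 3) in spleen and 28.2 CPM ± 10.5 (SD, n = 3) in bone marrow. The labels do not state which part of the gene was deleted, and a value summed over the whole gene does not check a deletion that leaves most of the transcript. These values do not settle the genotype labels, since 1 library labelled knockout in each cell type lies above all 3 labelled wild type, and every direction below is that of the libraries labelled knockout against those labelled wild type.

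**Figure D1:**
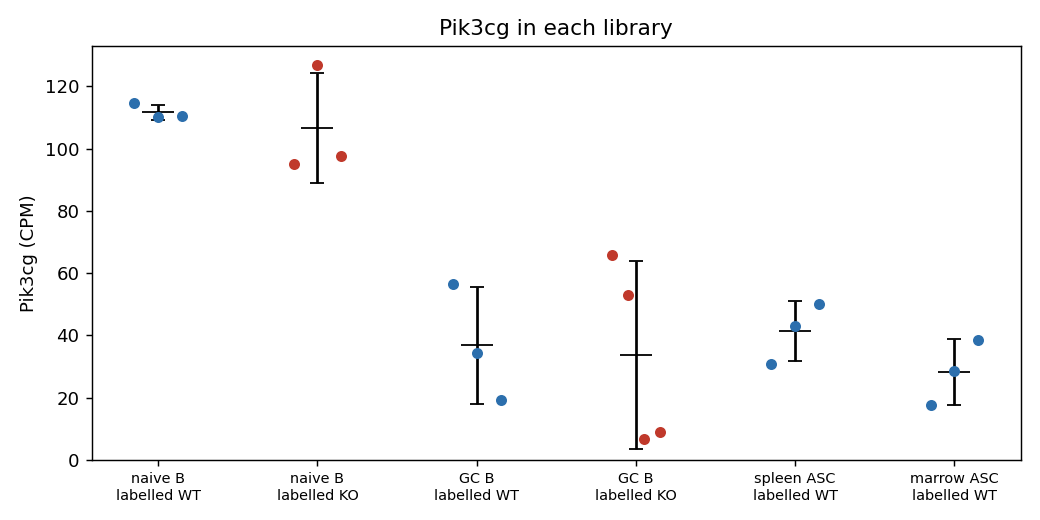
Pik3cg in each of the 19 libraries, in CPM on a linear axis, by group; points are libraries, the horizontal mark is the mean and the bar the SD. The libraries labelled knockout overlap those labelled wild type in both germinal centre and naive B cells.

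The germinal centre comparison asks how loss of Pik3cg changes cells that carry germinal centre surface markers. Several genes of the germinal centre programme, Rgs13, Gcsam, S1pr2 and Bcl6 among them, were high in the libraries labelled knockout and at or near 0 in those labelled wild type. Rgs13, a regulator of G protein signalling in germinal centre B cells, averaged 1079 CPM (725 to 1294, n = 4) and was listed at 0 in all 3 libraries labelled wild type, at least 7061-fold higher against a floor of 3 reads per library. Gcsam averaged 417 CPM ± 101 and the confinement receptor S1pr2 51.9 CPM ± 14.0, both also at 0 in the 3 libraries labelled wild type. Bcl6, the germinal centre transcription factor, was at 34.0 CPM ± 8.4 against 1.0 CPM ± 0.6 (log2 fold change 4.13, SE 0.65, limma adjusted p = 0.00384). Of 23 tested genes of the germinal centre list, 15 were higher and 2 lower, the same counts when adjusted over the list alone (camera adjusted p = 1.30e-08). With an estimated correlation the list had an adjusted p = 0.0692. The list summed to 6232 CPM ± 780 in labelled knockout and 2748 CPM ± 71 in labelled wild type, so other members were expressed in both. In naive B cells labelled wild type it summed to 2838 CPM ± 171, over 24 listed genes against 25. By this sum, described across separate tables, the germinal centre libraries labelled wild type did not exceed naive B cells. By other sums they did. The G2/M cell cycle list summed to 3816.6 CPM ± 562.5 in them against 127.6 CPM ± 47.0 in naive B cells labelled wild type. The G1/S list summed to 5413.0 CPM ± 624.6 against 876.9 CPM ± 37.8. Dark zone and light zone sums were also above those of naive B cells. B cell receptor signalling and interferon-stimulated sums, among others, were below them. Of 20 dark zone genes, 6 were higher and none lower in labelled knockout, also adjusted over the list alone (camera adjusted p = 0.00143, adjusted p = 0.365 with an estimated correlation). Rgs13 and Gcsam belong to the dark zone list as well as the germinal centre list. Mki67, a proliferation marker, was at 684 CPM ± 148 against 309 CPM ± 101. Neither cell cycle list passed: 3 of 31 G1/S genes were higher and none lower (camera adjusted p = 0.585). Of 32 G2/M genes, 2 were higher and none lower (camera adjusted p = 0.371).

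Markers of T cells, and some of monocytes and macrophages, were higher in the same libraries. Of 19 tested T cell markers, 14 were higher and none lower, also adjusted over the list alone (camera adjusted p = 9.97e-14, adjusted p = 0.118 with an estimated correlation). Cd3g averaged 176 CPM ± 67, Cd3d 123.9 CPM ± 52.7 and Trbc2 164 CPM ± 102 in the libraries labelled knockout, and each was at 0 in the 3 labelled wild type. Trac was at 198.7 CPM ± 71.2 against 0.60 CPM ± 1.04. Summed over the list, T cell markers reached 1816 to 3568 CPM in the libraries labelled knockout and 124.2 to 214.0 CPM in those labelled wild type (two-sided exact permutation p = 0.0286, the smallest that 4 against 3 libraries allow, adjusted p = 0.229 over 16 library measures). Of 16 monocyte and macrophage markers, 5 were higher, none lower and 11 did not pass (6 higher when adjusted over the list alone, camera adjusted p = 7.62e-06, adjusted p = 0.365 with an estimated correlation). Lyz2, the macrophage lysozyme, averaged 164 CPM ± 101 and the complement gene C1qb 132 CPM ± 147, both at 0 in the libraries labelled wild type. The summed monocyte and macrophage markers overlapped, at 634 to 4435 CPM against 598 to 670 CPM. The haemoglobin gene Hba-a1, whose reads may be shared with its near-identical copy, was at 829.7, 86.7, 7.8 and 25.8 CPM in the libraries labelled knockout and at 0 in those labelled wild type. Of 6 erythroid genes, 3 were higher and 1 lower (4 and 1 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.148). Dendritic cell markers, with 1 of 6 tested genes higher and 1 lower, also when adjusted over the list alone, did not pass (camera adjusted p = 0.396) and summed to 170.2 CPM ± 85.1 against 204.4 CPM ± 55.9. Too few NK and innate lymphoid, neutrophil or stromal and endothelial markers could be tested as lists. They summed to 121 to 298, 2.38 to 255 and 45.8 to 140.7 CPM in the libraries labelled knockout, and to 11.0 to 14.4, 0 to 0.60 and 6.7 to 21.1 CPM in those labelled wild type, without a test.

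Interferon-stimulated genes were also higher, with 10 of 22 higher and none lower (11 when adjusted over the list alone, camera adjusted p = 4.83e-06). This list kept its call with an estimated correlation (camera adjusted p = 0.0493). Over 31 listed genes it summed to 1987 CPM ± 170 in labelled knockout and 585 CPM ± 32 in labelled wild type. In naive B cells labelled wild type it summed to 1842 CPM ± 179 over 34 listed genes. By these sums, described across separate tables, the libraries labelled knockout were near naive B cells and those labelled wild type lay below them. Ifi209 was at 477 CPM ± 5 in germinal centre libraries labelled knockout against 69.04 CPM ± 7.23 in those labelled wild type. Of 29 B cell receptor signalling genes, 12 were higher and 2 lower (13 and 2 when adjusted over the list alone, camera adjusted p = 0.00120, adjusted p = 0.365 with an estimated correlation), among them the complement receptor Cr2 at 210 CPM ± 60 against 14.6 CPM ± 7.8. Of 28 naive follicular genes, 12 were higher and 4 lower (13 and 6 when adjusted over the list alone, camera adjusted p = 0.0412, adjusted p = 0.518 with an estimated correlation). Their sum leaned the other way, at 60481 CPM ± 3847 in labelled knockout against 75100 CPM ± 10037 in labelled wild type, with overlapping ranges. The transcription factor Ebf1 was at 303 CPM ± 56 against 89.3 CPM ± 3.5. The low-affinity IgE receptor Fcer2a went the other way, at 62.3 CPM ± 16.04 against 1925 CPM ± 468. Of 13 mitochondrially encoded transcripts, 8 were higher and none lower, also adjusted over the list alone (camera adjusted p = 0.0127, adjusted p = 0.518 with an estimated correlation), with mt-Cytb at 12283 CPM ± 1755 against 6515 CPM ± 1195. Mitochondrial genes took 3.61% ± 0.29 of the total against 2.24% ± 0.18.

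Some genes of the unfolded protein response, glycolysis and lipid synthesis were higher in the libraries labelled wild type, though their lists lost their calls with an estimated correlation. Xbp1, a transcription factor of the unfolded protein response and plasma cells, was at 3023 CPM ± 655 (SD, n = 3) against 478 CPM ± 84 (SD, n = 4) in those labelled knockout, a log2 fold change of −2.65 (SE 0.19, limma adjusted p = 9.64e-05). Prdm1 and Irf4, transcription factors of plasma cell differentiation, were at 82.2 CPM ± 23.1 against 7.1 CPM ± 9.6 (limma adjusted p = 0.0261) and at 144 CPM ± 32 against 26.7 CPM ± 14.7 (limma adjusted p = 0.00570). Of 30 plasma cell genes, 7 were lower in labelled knockout and 3 higher (12 and 4 when adjusted over the list alone, camera adjusted p = 0.00853, adjusted p = 0.365 with an estimated correlation). Of 40 unfolded protein response genes, 13 were lower and none higher (17 when adjusted over the list alone, camera adjusted p = 7.04e-07, adjusted p = 0.365 with an estimated correlation).

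Glycolysis had 8 of 18 genes lower in labelled knockout and none higher (9 when adjusted over the list alone, camera adjusted p = 3.86e-06, adjusted p = 0.0692 with an estimated correlation), with Aldoa at 337 CPM ± 35 against 1045 CPM ± 119. Cholesterol and fatty acid synthesis had 4 of 25 lower and none higher (7 when adjusted over the list alone, camera adjusted p = 1.93e-04, adjusted p = 0.103 with an estimated correlation), with Idi1 at 106 CPM ± 23 against 448 CPM ± 105. Light zone genes had 13 of 30 lower and 3 higher (15 and 4 when adjusted over the list alone, camera adjusted p = 1.06e-04, adjusted p = 0.288 with an estimated correlation). NF-kB and CD40 response genes had 10 of 23 lower and 2 higher (12 and 2 when adjusted over the list alone, camera adjusted p = 1.62e-04, adjusted p = 0.227 with an estimated correlation). The activation marker Cd83 was at 967 CPM ± 200 against 2736 CPM ± 604, and the oxysterol receptor Gpr183 at 94.7 CPM ± 33.4 against 591 CPM ± 99. Autophagy and lysosome genes had 5 of 24 lower and none higher (10 lower and 1 higher when adjusted over the list alone, camera adjusted p = 0.00666, adjusted p = 0.365 with an estimated correlation). Apoptosis genes had 5 of 17 lower and none higher (6 lower and 1 higher when adjusted over the list alone, camera adjusted p = 0.0294, adjusted p = 0.365 with an estimated correlation), led by the cell cycle inhibitor Cdkn1a at 4.5 CPM ± 5.2 against 586 CPM ± 8. Nupr1 and Nqo1, both stress-response genes, were at 0 in the 4 libraries labelled knockout and at 111 CPM ± 35 and 108 CPM ± 18 in those labelled wild type.

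**Figure D2:**
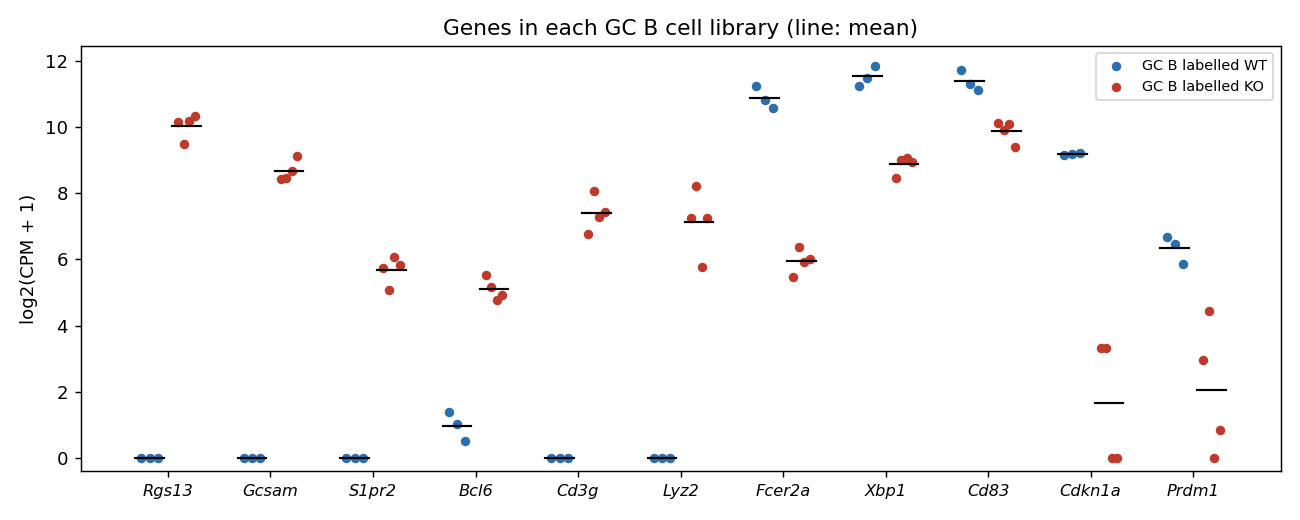
Expression of 11 genes in the 7 germinal centre B cell libraries as log2(CPM + 1); points are libraries and lines are group means. Rgs13, Gcsam, S1pr2, Cd3g and Lyz2 sit at 0 in the 3 libraries labelled wild type, while Fcer2a, Xbp1, Cd83, Cdkn1a and Prdm1 are higher there.

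In all, limma-trend called 1162 of 8522 tested genes in germinal centre B cells at an adjusted p under 0.05, with 728 higher and 434 lower in the libraries labelled knockout. Of the 34 gene lists large enough to test, 17 passed camera with a preset correlation and 2 with an estimated correlation. Myc (80.4 CPM ± 10.2 against 88.0 CPM ± 12.9), Cxcr4 (20.1 CPM ± 6.3 against 21.3 CPM ± 7.0) and Pik3cd (43.4 CPM ± 18.9 against 60.3 CPM ± 9.5) did not pass. Lists that did not pass had a smallest adjusted p of 0.0849, that of FOXO1 target genes. Among these, immunoglobulin constant genes had a positive median and mean with a negative test direction, and for marginal zone genes and chemokine receptors the median and mean differed in sign. The count was 732, 603 and 712 genes without replicate 1, 2 or 3 of the libraries labelled wild type. Of these, 531, 427 and 502 were higher and 201, 176 and 210 lower in labelled knockout, so the lower calls fell most. It was 432 without both labelled-knockout replicate 1, which held the most haemoglobin RNA, and labelled-wild-type replicate 3. In the latter the Y-linked gene Ddx3y was at 159 CPM and Xist at 0. With voom on estimated reads it was 735. These last 2 counts were chosen after the data were seen.

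**Figure D3:**
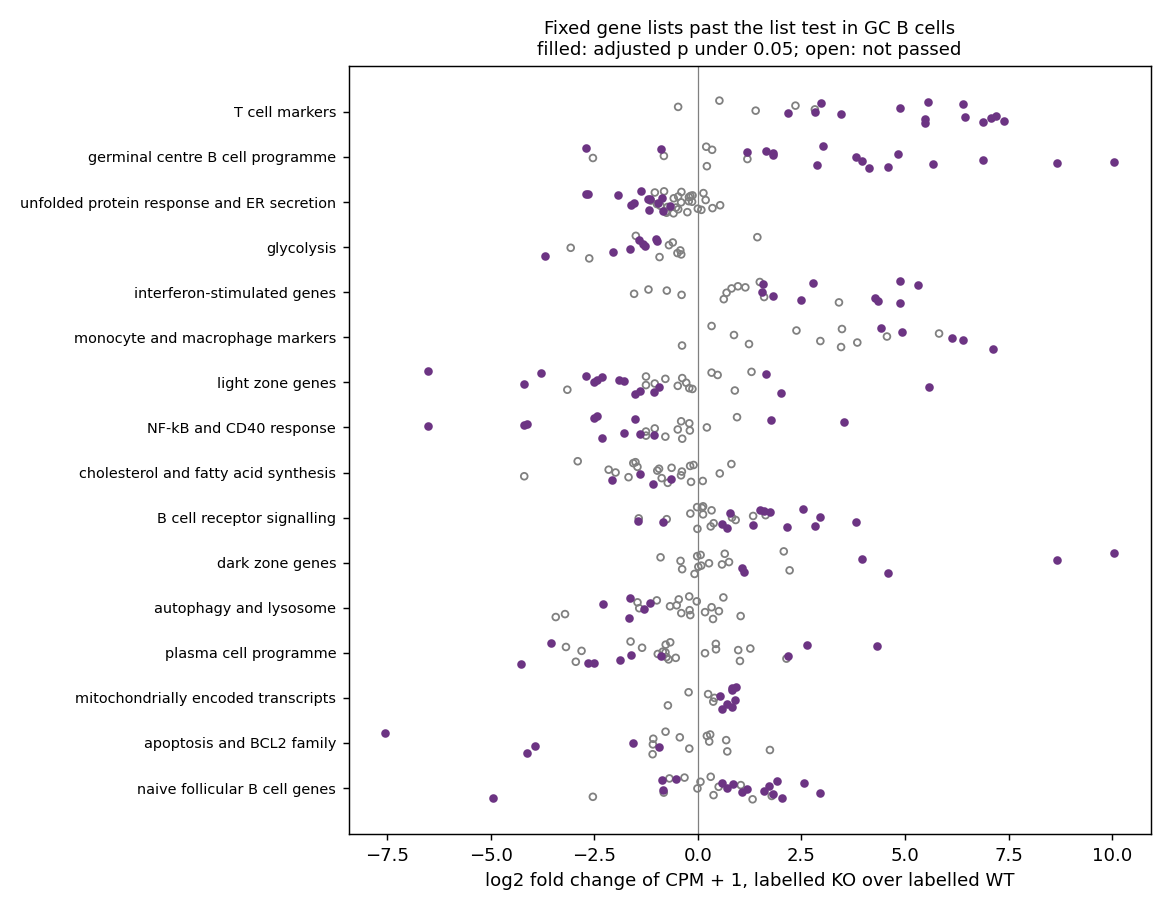
Log2 fold change of CPM + 1, labelled knockout over labelled wild type, for each tested member of 16 gene lists that passed the list test in germinal centre B cells; filled points passed an adjusted p of 0.05 and open points did not. Of the 16 lists drawn, 8 lean higher and 8 lower in the libraries labelled knockout.

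The naive comparison asks the same of resting B cells. No gene passed: limma-trend called 0 of 8832 genes, with a smallest adjusted p of 0.728, and voom also called 0. At an unadjusted p under 0.05 there were 587 genes, 325 higher and 262 lower, where uniform p-values give 441.6 and the highest of the other splits of these 6 libraries gave 532. Mitochondrially encoded transcripts had higher values in the libraries labelled knockout, with mt-Cytb at 4994 CPM ± 828 (SD, n = 3) against 2670 CPM ± 480 (SD, n = 3) and mt-Atp6 at 3008 CPM ± 201 against 1645 CPM ± 378.8. Their list of 13 genes had a median log2 fold change of 0.68, with 10 higher when adjusted over the list alone and none over all genes (camera adjusted p = 1.09e-09, adjusted p = 0.795 with an estimated correlation). Mitochondrial genes took 2.31% ± 0.16 of the total in labelled knockout and 1.56% ± 0.20 in labelled wild type, where 3 against 3 libraries allow no two-sided exact permutation p below 0.1, the value found. Cytosolic ribosomal protein genes (53 tested) had a median log2 fold change of −0.19 with no member past the threshold, over all genes or adjusted over the list alone (camera adjusted p = 3.07e-07, adjusted p = 0.795 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes (48 tested) had a median of −0.15, likewise with no member past the threshold, over all genes or adjusted over the list alone (camera adjusted p = 0.00167, adjusted p = 0.795 with an estimated correlation). Many ribosomal protein genes have processed pseudogenes that can share their reads.

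Among genes with the smallest unadjusted p in naive B cells were Senp1, a SUMO protease, at 67.4 CPM ± 8.8 in labelled knockout against 26.3 CPM ± 1.2, and Yipf6 at 24.3 CPM ± 3.2 against 61.2 CPM ± 15.1, neither past the threshold. Xbp1 was at 273 CPM ± 35 against 359 CPM ± 29, Irf4 at 69.7 CPM ± 19.5 against 54.1 CPM ± 11.3, Foxo1 at 125 CPM ± 22 against 125 CPM ± 6 and Cd83 at 1363 CPM ± 208 against 1338 CPM ± 46. T cell markers summed to 585 CPM ± 19 and 604 CPM ± 41. Groups did not overlap for 13.6% of the genes, where chance gives 10%, and for 27.4% in germinal centre B cells, where chance gives 5.71%.

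The difference between the labelled genotypes was itself tested between germinal centre and naive B cells. The labels do not state whether both cell types came from the same mice. The series design gives as many mice of each genotype as there are germinal centre libraries, so some naive libraries may come from those mice. Germinal centre labelled-wild-type replicate 3 lacked Xist while every naive library had it. By Xist, no naive library thus came from the mouse of that replicate. The fit treats the 13 libraries as independent, which was checked only through the replicate numbers, and that check cannot show it. Among 6969 genes tested in both, limma-trend found that 580 differed, 375 with a germinal centre effect above the naive effect and 205 below it, and 541 of these were also called in germinal centre B cells. Rgs13 differed by 10.19 on the log2 scale, Xbp1 by −2.26 and Fcer2a by −4.95. No call was shared, since naive B cells had none. At an unadjusted p under 0.05, 61 genes were higher in both where independent lists give 46.6, and 40 were lower in both where they give 23.9. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.042 and a Spearman rho of 0.057.

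Antibody-secreting cells were profiled only in mice labelled wild type, and their levels are described without a test because each table was made separately. Immunoglobulin genes and Jchain, the joining chain of IgA and IgM, took 74.0% ± 2.4 (SD, n = 3) of the total in spleen and 81.4% ± 3.0 (SD, n = 3) in bone marrow, against 4.02% ± 0.13 in naive and 11.4% ± 3.8 in germinal centre libraries labelled wild type. Igkc was the most abundant gene, at 295822 CPM ± 21949 in spleen and 311997 CPM ± 14274 in bone marrow. Igha followed at 139750 CPM ± 53739 and 191274 CPM ± 12963, and Jchain at 107061 CPM ± 1407 and 139410 CPM ± 12914. Igha made up 71.7% ± 24.5 of heavy-chain constant-region CPM in spleen and 89.7% ± 8.2 in bone marrow, and Ighm 15.1% ± 11.5 and 5.56% ± 6.59. Xbp1, at 4389 CPM ± 502 and 3684 CPM ± 59, the chaperone Hspa5, at 4139 CPM ± 683 and 2241 CPM ± 700, and the ubiquitin gene Ubb, at 4480 CPM ± 857 and 2652 CPM ± 299, were each among the 10 most abundant genes in spleen, bone marrow or both. Unfolded protein response genes summed to 21897 CPM ± 1954 in spleen and 13692 CPM ± 1461 in bone marrow.

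Prdm1 was at 84.98 CPM ± 40.4 in spleen and 61.7 CPM ± 17.0 in bone marrow, beside 82.2 CPM ± 23.1 in germinal centre and 2.66 CPM ± 4.45 in naive libraries labelled wild type. Cd83 was at 24.7 CPM ± 8.0 and 2.63 CPM ± 2.28, beside 2736 CPM ± 604 and 1338 CPM ± 46. Mki67 was at 44.3 CPM ± 9.7 and 15.9 CPM ± 10.8. Neutrophil markers summed to 11.5 CPM ± 16.02 in spleen and 209 CPM ± 132 in bone marrow, and T cell markers to 262 CPM ± 70 and 137 CPM ± 27. Because immunoglobulin transcripts fill most of each library, every other gene is diluted in CPM.

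**Figure D4:**
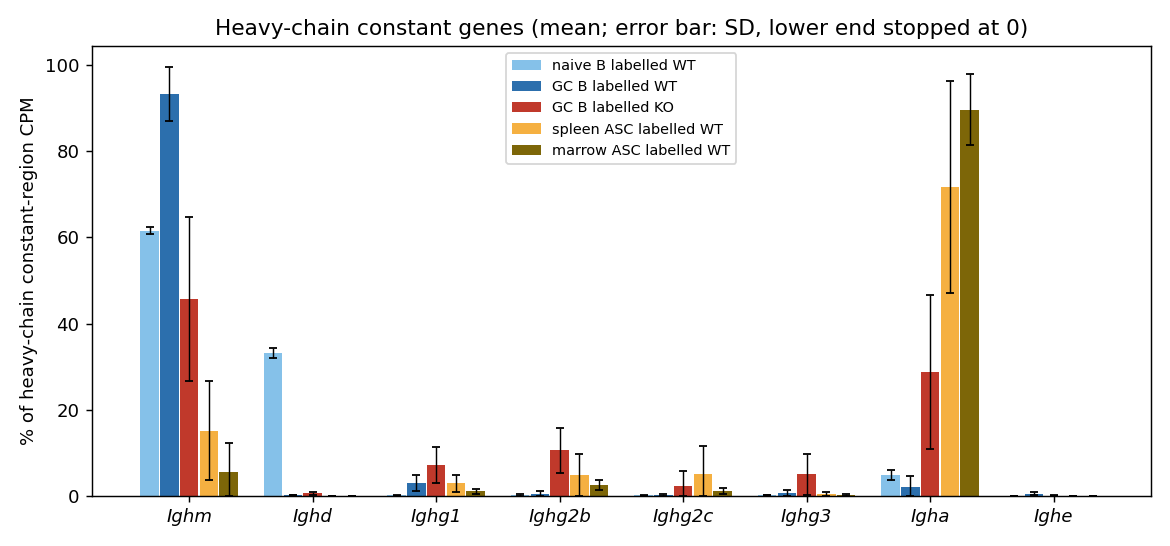
Share of each heavy-chain constant gene in the heavy-chain constant-region CPM, in percent; bars are means, error bars the SD with the lower end stopped at 0, n = 3 per group and 4 for germinal centre B cells labelled knockout. Igha leads in both kinds of antibody-secreting cell, and Ighm makes up 93.3% in germinal centre libraries labelled wild type and 45.7% in those labelled knockout.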

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

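All tests of explanations in this part, the counts of other splits included, were chosen after the results were seen. Several germinal centre genes at or near 0 in the germinal centre libraries labelled wild type were weighed first. Lower depth is argued against as the cause, since the shallowest of these libraries held 19.6 M estimated reads and the deepest labelled knockout 19.04 M. The libraries labelled wild type may hold B cells other than germinal centre B cells, or be mislabelled. The effective number of kappa variable genes was at least 30.7 in them and at most 17.4 in those labelled knockout. For the heavy chain the ranges overlapped (12.9 to 28.2 against 3.24 to 22.1). Variable-gene numbers do not measure germinal centre identity, so they cannot decide this, and it stays open. If the labels hold, a loss of Pik3cg acts in the mice labelled knockout. It would then not by itself account for values near 0 in the libraries labelled wild type. Whether the Pik3cg genotype adds to the difference between the groups stays open, because genotype and library set cannot be told apart. Pik3cg itself gave a log2 fold change of −0.60 with an interval across 0.

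T cell transcripts in the germinal centre libraries labelled knockout were weighed next. T cells or their RNA in these sorts stay open as a source. That 14 of 19 tested T cell markers were higher, Cd3g and Trbc2 at 176 and 164 CPM among them, is the pattern itself and does not favour 1 cause. Of the 24 markers listed, 4 reach 10 CPM in naive libraries labelled wild type and 4 are also in another list. The labels give CD95 and GL7 as the gate and name no marker that excludes T cells. Lower depth is argued against by the same 19.6 M reads. Summed NK and innate lymphoid, neutrophil and stromal markers were also higher in the same libraries without overlap. The macrophage, erythroid and dendritic sums overlapped. In naive B cells the T cell markers summed to 585 CPM ± 19 in labelled knockout and 604 CPM ± 41 in labelled wild type, so no rise showed there. Only 2 of these markers could be tested in naive B cells (median log2 fold change 0.087). An effect of the genotype limited to germinal centre B cells cannot be told apart.

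Mitochondrial transcripts higher in the naive libraries labelled knockout were weighed last. The same 13 transcripts also leaned higher in germinal centre libraries labelled knockout, with a median log2 fold change of 0.59. That list likewise lost its call with an estimated correlation (camera adjusted p = 0.518). An immediate-early stress response during sorting is argued against: the 22 immediate-early genes tested had a median log2 fold change of 0.073 and a highest of 0.31, below the mitochondrial median of 0.68. Damage to the cells without such a response was not tested. An effect of the genotype cannot be told apart from a spread shared by these genes, with a camera adjusted p = 0.795 with an estimated correlation.

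Other splits of the libraries into groups of the same sizes were compared with the real one. In germinal centre B cells, 1 of 35 splits, the real one, gave as many as 1162 genes, and the highest other gave 3. Chance is argued against for the gene count, at the smallest share that 35 splits allow (0.0286). Such splits do not tell genotype from other differences between the sets of libraries. For the lists, 2 of 35 splits gave as many as 17, the highest other 18, and chance is not excluded. In naive B cells, 10 splits are too few for a share under 0.05: the real split gave 0 genes and the highest other 0, as in all 10, and for lists the real split gave 3 and the highest other 3, in 2 of the 10. For the difference of effects, 3 of 100 drawn splits, the real one included, gave as many as 580 genes, and all 3 kept the real germinal centre labels. The highest other, 662, exceeded the real count with other naive labels, while with other germinal centre labels the highest was 9. These splits therefore restate those of the germinal centre libraries and do not exclude chance for a difference between the cell types.

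Single libraries stood far from the rest of the 4 germinal centre libraries labelled knockout in 10 of 99 values. The limit used gives about 1 in 20 by chance, or 4.95, for independent values with a normal spread. CPM values near 0 are skewed and some of these genes vary together, so that rate is not a test here. For Ccl22, Serpine2 and Pik3r5 the other libraries reached at most 1.55 CPM. Replicate 1 was apart for Hba-a1 at 829.7 CPM, Hbb-bt at 99.6 CPM, Ccl22 at 10.9 CPM and its 12068 genes at 1 CPM or more. Replicate 2 was apart for Cd3d at 202.7 CPM, Trbc2 at 314 CPM and Hexa at 36.2 CPM. Replicate 3 was apart for Atp5j at 447.5 CPM, Pik3r5 at 27.9 CPM and Serpine2 at 15.0 CPM.

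For 50 of 87 named genes, the effect in germinal centre B cells differed from that in naive B cells by the limma test of the difference. Over all genes it was 580 of 6969, and the higher share is built in by the choice of named genes, most of them called in germinal centre B cells, while naive B cells had no call. Log2 effects were above the naive ones for Rgs13 by 10.19, Lyz2 by 7.54, Hba-a1 by 7.12, Fos by 6.01, Hbb-bt by 5.63, Ccr6 by 5.47, Phf11b by 4.996, Cr2 by 4.07, Zbtb20 by 3.29, Ifi209 by 2.71, Sesn1 by 1.77, Cd22 by 1.72, Ltb by 1.69, Ptprc by 1.69, Ebf1 by 1.64, Ms4a1 by 1.32, Mier1 by 1.24, Ucp2 by 1.18, Cox6b1 by 1.00, Ndufs8 by 0.94, Atp5a1 by 0.92, Atp5j by 0.91 and Slbp by 0.84. The difference was −4.95 for Fcer2a, −4.89 for Il5ra, −3.69 for Ebi3, −3.47 for Glipr1, −2.85 for Irf4, −2.78 for Gpr183, −2.69 for Ddit3, −2.53 for Plscr1, −2.52 for Cd44, −2.33 for Hexa, −2.26 for Xbp1, −2.05 for Ighm, −1.91 for Ccnd2, −1.90 for Mzb1, −1.75 for Phgdh, −1.70 for Ccng1, −1.66 for Bax, −1.58 for Aldoa, −1.55 for Idi1, −1.52 for Cd83, −1.49 for Necap2, −1.32 for Pkm, −1.21 for Rpn2, −1.20 for Nfkbia, −1.15 for Lamp2, −1.01 for Klf6 and −0.86 for Eno1. Fitted values of genes at 0 in a group depend on the pseudocount.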

How the results depend on the processing

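Voom on estimated reads and the fits without 2 doubted libraries were chosen after seeing the data. Under the planned changes of pseudocount, filter, scaling, weights, robust estimation and threshold, germinal centre B cells gave 1021 to 1720 genes and naive B cells 0. Without a filter 25 lists passed in germinal centre B cells, 16 higher and 9 lower, against 17 with it, 8 and 9. Rescaling to the same total, which CPM nearly has already, left the counts of genes and lists as they were. The germinal centre count was 735 with voom, of which 711 were shared, and 432 without the 2 doubted libraries, of which 409 were shared; the second has fewer samples, and the cause of the first was not tested. Leaving out each library gave 603 to 1134 genes and 15 to 18 lists in germinal centre B cells, 0 genes and 2 to 4 lists in naive B cells, 398 to 680 genes for the difference of effects, and Pik3cg log2 fold changes of −1.11 to −0.06 and −0.21 to −0.0053; without the 2 doubted libraries Pik3cg was at −1.50. With an estimated correlation, 2 lists passed in germinal centre and 0 in naive B cells; fry gave 23 and 0, and the cause was not tested. At an unadjusted p under 0.05 the overlap was 101 genes. Replicate numbers gave no sign of pairing (correlations of deviations 0.079, 0.00057 and 0.0078 in germinal centre and −0.047, 0.038 and −0.034 in naive B cells), and a replicate block gave 0 genes in naive B cells. In germinal centre B cells the block also leaves out labelled-knockout replicate 4: it gave 828 genes, 17 lists and 433 genes for the difference, against 1031, 15 and 627 without that library alone. Between the cell types replicate numbers gave no sign of pairing either, at 0.034, −0.015 and −0.0094 in labelled knockout and −0.036, −0.0081 and −0.022 in labelled wild type. Such values cannot show that libraries come from different mice, since libraries of the same mouse need not share deviations or a number. The replicate numbers are those of the sample titles. In the germinal centre table, labelled-wild-type 2 and 3 are numbered the other way round, where the correlations between the labelled genotypes would be 0.026 and 0.0043. Replicate 3 of these also carries a sequencing sample number far from those of the other 6 libraries. Of the 89 named genes that were called in germinal centre B cells none changed sign, but 40 kept their call under every alternative that tested them and 72 in every fit without a library, with 73 and 53 results no longer past the threshold. Among named genes, signs changed for uncalled ones. Cxcr4 in germinal centre B cells was at 0.28 without the 2 doubted libraries and −0.36 to 0.12 over the fits without a library. In naive B cells, Klf2 was at 0.0026 and Cd83 at −0.00031 with array weights, and Foxo1 at 0.0065 with voom. Over the fits without a library, naive Myc ran from −0.24 to 0.28, Foxo1 from −0.15 to 0.068, Klf2 from −0.33 to 0.33, Cd83 from −0.098 to 0.12 and Cxcr4 from −0.0085 to 0.57, and the cause was not tested. As CPM of genes outside the immunoglobulins, Xbp1 was at 16896 in spleen and 20173 in bone marrow antibody-secreting cells. Count tests with edgeR or DESeq2 were not run, since whole reads could not be recovered. At these depths, group sizes and spreads between replicates, the simulated data gave few calls for 2-fold changes.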

Other observations

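Variable-gene usage was looked at after the data were seen, and no test of a difference was run. Over 98 kappa variable genes found in all tables, the effective number (the inverse of the summed squared shares) was 13.5 ± 4.0 (SD, n = 4) in germinal centre B cells labelled knockout and 32.7 ± 1.7 (SD, n = 3) in those labelled wild type, beside 39.7 ± 1.2 in naive B cells, 33.9 ± 3.2 in spleen and 35.4 ± 2.6 in bone marrow antibody-secreting cells labelled wild type. Over 102 heavy-chain variable genes it was 12.2 ± 7.7 in germinal centre B cells labelled knockout and 20.6 ± 7.6 in those labelled wild type, with overlapping ranges, both below the 40.96 ± 3.24 of naive B cells, 35.8 ± 3.3 of spleen and 34.9 ± 3.5 of bone marrow antibody-secreting cells labelled wild type. Ighv4-1 took 53.3% of the heavy-chain variable total in labelled-knockout replicate 4, and Ighv11-2 took 24.5% in labelled-wild-type replicate 2. Variable genes resemble each other, so their reads can be split uncertainly.

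Heavy-chain class is described without a test. In the germinal centre libraries, Ighm made up 93.3% ± 6.2 of heavy-chain constant-region CPM in those labelled wild type and 45.7% ± 18.99 in those labelled knockout, while Igha made up 1.96% ± 2.59 and 28.7% ± 17.9, with overlapping ranges (0.0949% to 4.92% and 3.23% to 42.5%). Ighe was at 139 CPM ± 40 in those labelled wild type and 6.6 CPM ± 8.8 in those labelled knockout. Within 10 Mb of Pik3cg on chromosome 12, 5 of 33 tested genes were called in germinal centre B cells, 15.2% against 13.6% of all genes, and 0 of 36 in naive B cells.

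Xist was at 0 and Ddx3y at 159 CPM in germinal centre labelled-wild-type replicate 3. In the other 6 germinal centre libraries Ddx3y was at 0, and Xist ranged from 11.6 to 205.2 CPM. Among naive libraries Xist, the only member of the sex-linked list found there, was at 76.2 to 122.4 CPM in those labelled wild type. In naive libraries labelled knockout it was at 116.4 to 153.4 CPM. No naive library thus had Xist at 0, as germinal centre labelled-wild-type replicate 3 did, so by Xist none came from the mouse of that replicate.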
